A study of Homo sapiens with 20 samples.

How the data were processed

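The deposited table of raw signals holds linear bead-array intensity values for 47323 probes on 20 arrays, exported by the authors before normalization; the software and settings behind the export are not given in the sources used here. The deposited normalized table holds linear intensity values. Its column median is 97.1 in every column, and quantile normalization of the raw table without background correction gave the same values. No column was log-transformed or centered in either table. Array scanning and chip layout are not given in the sources used here.

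The raw table was used. The plan written before the data were examined was background correction from negative control probes with limma's neqc, and a filter on the deposited detection p-values. The table contains neither controls nor detection p-values, so limma's normexp correction was run on the signals themselves with an offset of 16, followed by quantile normalization and log2. A detection p was estimated for each array from its background, taken as the mode of its signals with the spread of the values below the mode. Probes with an estimated detection p under 0.01 on at least 4 arrays were kept: 23619 probes, of which 16831 name a gene. Of all probes, 30113 name 1 gene and the other 17210 name no single gene. The annotation holds 8 probes that name several genes, which were not assigned to any. A gene with several kept probes is counted by the brightest of them, which gave 12696 genes. Signals near background compress changes, and where a gene lay at background in a whole group the difference is given as a lower bound. Sequencing depth does not apply to arrays, where the number of arrays and the signal over background limit precision.

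A linear model in limma had a mean for each of the 5 groups (15 residual degrees of freedom, 4.44 prior), with moderated variances from limma's eBayes. CRPC against intact compares the average of CRPC1 and CRPC2 with that of Intact1 and Intact2, GNX is compared with the same average, and CRPC with GNX. Intact2 with Intact1, CRPC2 with CRPC1, and the interaction of these were tested as well. Every adjusted p for a gene is a Benjamini-Hochberg value from limma over all 23619 kept probes, at a threshold of 0.05. A count "adjusted over the list alone" adjusts limma's p-values over the measured genes of 1 list. Every gene named with a difference was measured with 4 tumors per group. Each gene has 1 variance shared by all 5 groups, so a standard error also reflects the spread of groups outside the comparison.

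The gene lists were fixed before the data were examined: 37 lists with 708 genes, 652 of them in the probe table and 508 measured. Some genes are on more than 1 list. Lists with at least 5 measured genes were tested, 34 in all. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists of a comparison, and again with an estimated correlation. The counts of lists past the threshold were 6 (0 with an estimated correlation) for CRPC against intact, 14 (3) for GNX against intact, 12 (1) for CRPC against GNX, 18 (1) for Intact2 against Intact1, 8 (0) for CRPC2 against CRPC1 and 13 (0) for the interaction.

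Genes were named by a rule fixed before the data were examined. For the comparisons among intact, GNX and CRPC tumors these are the 6 genes that rose most and the 6 that fell most among called genes whose arrays do not overlap, up to 3 called members of each list described, by smallest adjusted p, and a set of androgen-related genes wherever measured: KLK3, TMPRSS2, FKBP5, ERG, HSD17B6, AKR1C3, UGT2B15 and UGT2B17. CYP17A1 was also in that set, and its probe was not among the kept probes. For the other comparisons 3 genes each way were named, and up to 2 members of a list without called genes. Some genes were not analysed here. Genes of the UGT2B, AKR1C, MT1, HLA and HSPA1 families have near-identical copies, and their probes may share signal. Tumor numbers do not pair tumors across groups, so the main model has no pairing, and a block by tumor number is an alternative only.

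The model and the list test were run on simulated log2 values of the kept probes. Each gene was drawn independently with its own spread, without array sets, normalization or filtering. For GNX against intact the model recovered 47.8%, 94.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale, for CRPC against intact 68.7%, 92.5% and 98.5%, and for Intact2 against Intact1 40.3%, 91.0% and 100%. For CRPC against GNX it recovered 53.7%, 95.5% and 100%, for CRPC2 against CRPC1 52.2%, 85.1% and 98.5%, and in the interaction 7.46%, 73.1% and 95.5%. False calls in this order were 3, 4, 4, 3, 7 and 2. Of 34 lists camera called 1, the one that had been shifted. Because the simulated genes were independent, this cannot show false list calls among correlated genes. Programs were R 4.3.3 and limma 3.58.1.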

Results

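Gene expression was measured on Illumina human bead arrays in 20 tumors grown from VCaP cells, a human prostate cancer line, in the prostate of athymic nude mice. The tumors formed 5 groups of 4. Intact1 and Intact2 were collected 3 to 14 weeks after inoculation from mice with testes, GNX 1 day after castration, and CRPC1 and CRPC2 3 to 14 weeks after castration, when growth had become castration-resistant. The labels do not say what separates the groups numbered 1 from those numbered 2. The arrays held 47323 probes, and mean signals per array lay between 424 and 498 intensity units. Between 18266 and 21741 probes per array stood above the estimated background. After filtering, 23619 probes and 12696 named genes were tested. Values are log2 differences with the standard error of limma's fit, over 8 intact, 8 CRPC and 4 GNX tumors, unless another n is given; the number of arrays limits their precision.

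Arrays of the same group correlated between 0.972 and 0.994. Principal components 1, 2 and 3 held 21.5%, 20.5% and 14.6% of the variance. The second separated tumors 1 and 2 of every group from tumors 3 and 4, and the background level was 81.5 ± 2.40 (SD, n = 10) in the first array set and 76.6 ± 1.27 (SD, n = 10) in the second. No label names such sets. Each group has 2 tumors in each, so values fitted with the array set as a block, and within each set, are given beside counts and the list shifts described.

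**Figure D1:**
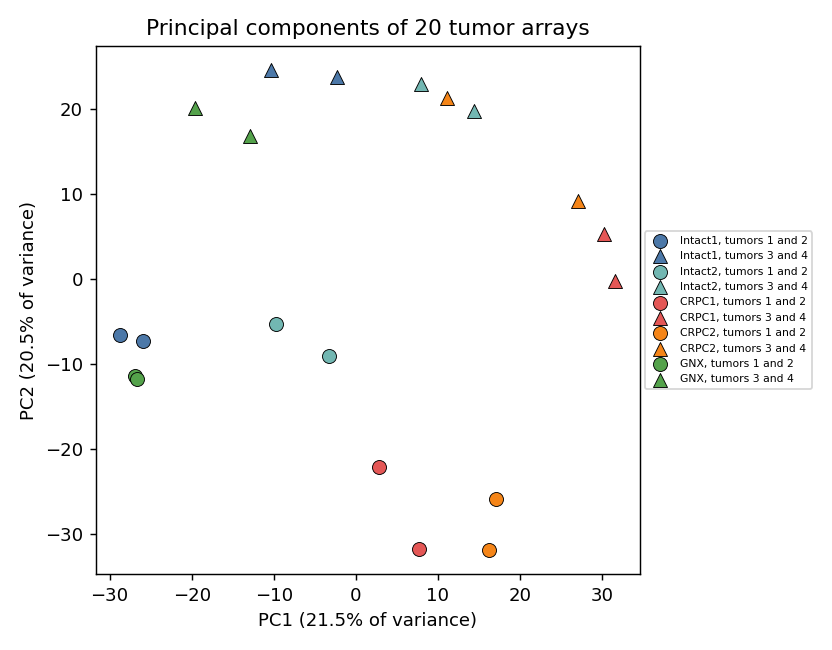
Principal components 1 and 2 of the 20 arrays, in units of the component scores, 1 point per tumor, colored by group and shaped by array set. The components hold 21.5% and 20.5% of the variance.

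The first comparison asks what changed in the tumors 1 day after castration. Kallikrein 2 (KLK2), an androgen-driven secreted protease, fell by 1.58 ± 0.15 on the log2 scale in GNX against intact tumors, from 13.33 ± 0.34 (SD, n = 8) to 11.75 ± 0.28 (SD, n = 4). SLC45A3, a prostate transporter, fell by 1.78 ± 0.14, PMEPA1, an inhibitor of TGF-beta signaling, by 1.59 ± 0.12, the serine protease TMPRSS2 by 1.13 ± 0.18 and the co-chaperone FKBP5 by 1.34 ± 0.17. The androgen-inactivating enzymes UGT2B15 and UGT2B17 rose by 1.92 ± 0.19 and 1.43 ± 0.16, and AKR1C3, which reduces androstenedione to testosterone, rose by 1.31 ± 0.17. DNA replication genes fell together, among them CDC45, a part of the replicative helicase, by 1.61 ± 0.17. In all, 1015 genes rose and 934 fell.

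**Figure D2:**
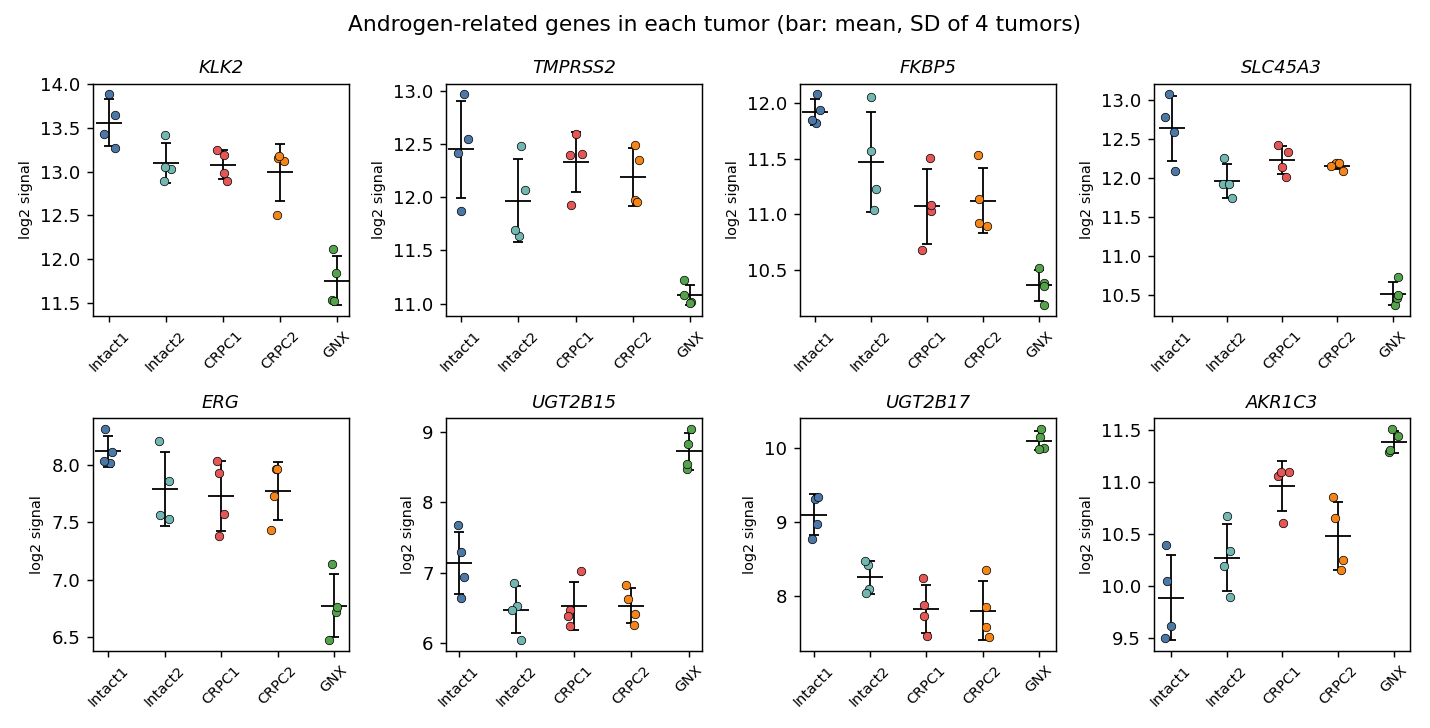
Log2 signal of 8 androgen-related genes in each of the 20 tumors, 1 point per tumor, with the mean and SD of the 4 tumors of each group. GNX tumors have the lowest levels of KLK2, TMPRSS2, FKBP5, SLC45A3 and ERG (brighter probe) and the highest of UGT2B15, UGT2B17 and AKR1C3.

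Among genes whose arrays did not overlap, the largest rises in GNX tumors were those of MGP, a matrix protein that inhibits calcification (2.35 ± 0.21), UGT2B15, the prostaglandin E2 receptor PTGER2 (1.91 ± 0.26, above background in 5 of 8 intact tumors), CYB561A3 (1.85 ± 0.25) and albumin, ALB (1.80 ± 0.19). The secreted protease HABP2 was not above background in any intact tumor and was at least 2.57-fold higher in GNX (adjusted p = 1.31e-06). The largest falls among such genes were those of CYP1B1, an estrogen-hydroxylating cytochrome P450 (-2.32 ± 0.17), neuropeptide Y, NPY (-2.20 ± 0.24), the glucose transporter SLC2A3 (-1.99 ± 0.32) and the alpha tubulin TUBA3D (-1.91 ± 0.16). STEAP4, a metalloreductase, and the growth hormone receptor GHR were above background in all 8 intact tumors and in 0 of 4 GNX tumors. They were at least 3.25-fold and 1.75-fold lower there (adjusted p = 9.63e-05 and 0.00167). The other adjusted p-values in this paragraph lie between 8.75e-08 and 0.000357. KLK3, which encodes prostate-specific antigen, differed by -0.58 ± 0.25 (adjusted p = 0.156), and HSD17B6, which oxidizes androstanediol to dihydrotestosterone, by -0.08 ± 0.20 (adjusted p = 0.9). MGP is also on the list of host connective tissue markers, where FSTL1 fell and the other 7 of 9 measured genes did not pass.

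Of 35 measured genes on the fixed list of androgen-induced genes, 19 fell and 2 rose in GNX tumors (24 and 3 adjusted over the list alone). Its median was -0.56 (adjusted p = 1.04e-13 in camera; adjusted p = 0.0385 with an estimated correlation). The list of androgen-repressed genes had 6 of 12 rise and 0 fall (7 rose adjusted over the list alone), including the intestinal disaccharidase SI (1.67 ± 0.11), with a median of 0.67 (adjusted p = 2.36e-05; adjusted p = 0.00719 with an estimated correlation). Within tumors 1 and 2 the medians of these lists were -0.57 and 0.71, and within tumors 3 and 4 -0.57 and 0.63. With the array set as a block their adjusted p-values were 3.23e-13 and 3.81e-05. The androgen-repressed list holds UGT2B15, UGT2B17, UGT2B10, UGT2B11 and UGT2B28, whose probes may share signal, so its counts may not be of separate genes.

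Of 28 DNA replication genes, 25 fell and 0 rose (26 fell adjusted over the list alone), with MCM10 at -1.27 ± 0.13 and GINS2 at -1.23 ± 0.13, both of the origin-firing machinery. The list's median was -0.77 (adjusted p = 9.36e-26; adjusted p = 0.0385 with an estimated correlation; 1.56e-24 with the array set as a block). It was -0.81 within tumors 1 and 2 and -0.77 within tumors 3 and 4. Of 30 mitosis genes, 4 fell (5 adjusted over the list alone), with a median of -0.24 (adjusted p = 0.000301; adjusted p = 0.542 with an estimated correlation). The spindle checkpoint gene MAD2L1 fell by 0.73 ± 0.13 (-0.27 and not called by another kept probe). The mitotic kinases AURKB (-0.52 ± 0.14) and TTK (-0.39 ± 0.12) passed in the fit to all arrays. AURKB was no longer called without GNX tumor 2 or 4 (adjusted p = 0.0835 to 0.0858), nor TTK without Intact1 tumor 3, Intact2 tumor 2 or 3, or GNX tumor 1, 2 or 3 (adjusted p = 0.0569 to 0.12). Median mitosis differences were -0.31 within tumors 1 and 2 and -0.15 within tumors 3 and 4, and the blocked adjusted p was 0.000343. Against Intact1 alone 5 mitosis genes fell (median -0.33), and against Intact2 alone 1 (median -0.11).

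Of 15 growth arrest genes, 5 rose and 1 fell (7 and 2 adjusted over the list alone), led by the stress-response gene SESN1 (0.91 ± 0.10), the cyclin CCNG2 (0.97 ± 0.16) and TP53INP1 (0.69 ± 0.12). Their median was 0.31 (adjusted p = 0.0339; adjusted p = 0.161 with an estimated correlation; 0.0281 with the array set as a block), with 0.24 within tumors 1 and 2 and 0.31 within tumors 3 and 4. That list was no longer called without Intact2 tumor 1 or GNX tumor 3 (adjusted p = 0.0553 to 0.0556). Against Intact1 alone its median was 0.44, with 5 genes rising and 1 falling, and against Intact2 alone 0.17 (adjusted p = 0.247), with 3 rising and 2 falling.

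Endoplasmic reticulum stress genes fell in GNX tumors. Of 19 measured genes of the unfolded protein response, 14 fell and 0 rose (14 fell and 1 rose adjusted over the list alone), led by the chaperone HSPA5 (-1.02 ± 0.11), MANF (-1.12 ± 0.13) and CRELD2 (-1.20 ± 0.15). The median was -0.57 (adjusted p = 2.67e-10; adjusted p = 0.0784 with an estimated correlation; 6.42e-10 with the array set as a block), -0.67 within tumors 1 and 2 and -0.50 within tumors 3 and 4. Against Intact1 alone 12 of these genes fell, and against Intact2 alone 9.

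Of 19 cholesterol synthesis genes, 6 fell (11 fell and 1 rose adjusted over the list alone), among them the sterol isomerase EBP (-0.70 ± 0.12), ACAT2 (-0.56 ± 0.12) and HMGCS1 (-0.86 ± 0.20). This list had a median of -0.32 (adjusted p = 5.26e-05; adjusted p = 0.208 with an estimated correlation; 0.000106 with the array set as a block), -0.36 and -0.31 within the array sets. Against Intact1 alone 9 fell and 1 rose (median -0.36), and against Intact2 alone 1 fell (median -0.25). The list of glucocorticoid-induced genes shares FKBP5 with that of androgen-induced genes. It had 6 of 15 fall and 1 rise (8 and 1 adjusted over the list alone), among them the transcription factors ZBTB16 (-1.69 ± 0.15, with -1.12 by another kept probe) and CEBPD (-1.12 ± 0.14). Its median was -0.44 (adjusted p = 0.000368; adjusted p = 0.169 with an estimated correlation; 0.000343 with the array set as a block), -0.53 and -0.44 within the sets. Against Intact1 alone that median was -0.13 (adjusted p = 0.0939), with 3 genes falling, and against Intact2 alone -0.91, with 9.

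Genes of hypoxia and glycolysis were lower in GNX than in the 8 intact tumors, where Intact1 and Intact2 differed. Of 18 hypoxia genes 10 fell (10 adjusted over the list alone), including NDRG1 (-1.07 ± 0.13), STC2 (-1.23 ± 0.21) and lysyl oxidase, LOX (-1.14 ± 0.21), with a median of -0.77 (adjusted p = 1e-05; adjusted p = 0.208 with an estimated correlation). Of 20 glycolysis genes 14 fell and 1 rose (19 and 1 adjusted over the list alone), including the phosphofructokinase PFKP (-0.96 ± 0.15, but -0.25 and not called by another kept probe) and PFKFB2 (-1.01 ± 0.18), with a median of -0.69 (adjusted p = 1.06e-09; adjusted p = 0.208 with an estimated correlation). NDRG1 is also on the list of androgen-induced genes. Against Intact1 alone, 2 hypoxia genes fell and 1 rose (median -0.03) and 4 glycolysis genes fell and 1 rose (median -0.24). Against Intact2 alone 13 and 18 fell, with medians of -1.25 and -1.06. The 9 metallothioneins, which bind zinc and copper, had 3 fall against all intact tumors (4 adjusted over the list alone), at a median of -0.38 (adjusted p = 0.0015; adjusted p = 0.208 with an estimated correlation), 0 fall against Intact1 alone and 6 against Intact2 alone. Within tumors 1 and 2 the medians of hypoxia, glycolysis and metallothionein genes were -0.72, -0.64 and -0.43, and within tumors 3 and 4 -0.80, -0.75 and -0.39. Blocked adjusted p-values were 3.07e-06, 1.06e-10 and 0.00103.

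The interferon list had 2 of 17 genes rise in GNX tumors (6 adjusted over the list alone), with a median of 0.22 (adjusted p = 0.0195; adjusted p = 0.431 with an estimated correlation; 0.0174 with the array set as a block). It was -0.05 within tumors 1 and 2 (adjusted p = 0.837) and 0.38 within tumors 3 and 4, 0.18 against Intact1 alone (adjusted p = 0.251) and 0.35 against Intact2 alone. Without GNX tumor 4 the median was 0.04 (adjusted p = 0.537) and without GNX tumor 3 it was 0.35 (adjusted p = 0.0107). Fatty acid synthesis genes had 5 of 17 fall (5 fell and 1 rose adjusted over the list alone), with a median of -0.13 (adjusted p = 0.0225; adjusted p = 0.276 with an estimated correlation; 0.0261 with the array set as a block), and -0.19 and -0.15 within the array sets, not passing in tumors 3 and 4 (adjusted p = 0.0624). Against Intact1 alone 3 fell (median -0.30), and against Intact2 alone 2 fell and 1 rose (median -0.11, adjusted p = 0.27). From both sets together the median was -0.06 without Intact2 tumor 2, and the call was lost without GNX tumor 2 (adjusted p = 0.0941).

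Across all genes, limma called 1949 of 12696 at an adjusted p of 0.05 and 3607 at an unadjusted p under 0.05. With median scaling, 1317 rose and 664 fell. The array set as a block gave 2299 genes, and fits within tumors 1 and 2 and within tumors 3 and 4 gave 868 and 719. GNX and intact tumors did not overlap at all for 10.2% of all genes, where chance gives 0.404%, and 1132 of these genes were called. Of 48 genes named for this comparison 46 were called. All 46 were called with the array set as a block and kept their direction within each set, where 41 and 39 passed. These genes were chosen from the same arrays, partly for not overlapping, so their kept direction is no separate support. Against Intact1 alone 1672 genes changed, and against Intact2 alone 1503. Of the 46 named calls 43 held against Intact1 alone, where PFKP (-0.36), STC2 (-0.46) and TTK (-0.40) did not pass (adjusted p = 0.0644 to 0.273). Against Intact2 alone 42 held, without AURKB (-0.43), TTK (-0.38), ACAT2 (-0.32) and HMGCS1 (-0.65; adjusted p = 0.0886 to 0.188). Host cell markers, of which ERG is left out because VCaP cells express it, had 1 rise and 1 fall of 32, with a median of -0.02. This array has human probes, which see mouse RNA only by cross-hybridization, and 33 of 85 listed host markers were measured. Host markers therefore tell little about host content in any comparison.

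The second comparison asks how castration-resistant tumors differed from tumors in intact mice. The olfactory receptors OR51E1 and OR51E2, both expressed in prostate, rose by 2.88 ± 0.27 and 1.97 ± 0.24, OR51E1 being above background in 1 of 8 intact and 8 of 8 CRPC tumors. The mineralocorticoid receptor NR3C2 rose by 1.86 ± 0.20 and the neuroendocrine granule protein SCG2 by 2.33 ± 0.31. ALDH1A1, which makes retinoic acid, fell by 2.56 ± 0.27, and HLA-DMB, which loads peptides on MHC class II, fell by 2.22 ± 0.23. TMPRSS2 differed by 0.05 ± 0.15 (adjusted p = 0.899) and KLK3 by 0.26 ± 0.20 (adjusted p = 0.506). In all, 897 genes rose and 819 fell.

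Among the largest rises of genes whose arrays did not overlap, the reticulon RTN1 changed by 1.59 ± 0.18, with 0.48 (called) and 0.06 (not called) by other kept probes, and another probe of NR3C2 gave 1.02. The glutamate receptor subunit GRIA2 and the ubiquitin ligase MARCHF4 were above background in 0 of 8 intact and 7 of 8 CRPC tumors and were at least 1.94-fold and 1.69-fold higher (adjusted p = 1.59e-05 and 4.19e-06). The largest falls of such genes were those of ENTREP1 (-2.63 ± 0.24, above background in 2 of 8 CRPC tumors), ALDH1A1, HLA-DMB, the cold-sensing channel TRPM8 (-2.05 ± 0.35), the fatty acid elongase ELOVL2 (-1.98 ± 0.19, above background in 3 of 8 CRPC tumors) and the collagen chain COL4A5 (-1.94 ± 0.19, with -1.21 by another kept probe). Adjusted p-values of these genes and those of the paragraph's other largest changes lie between 3.56e-06 and 0.000741. HSD17B6 rose by 0.87 ± 0.16 (adjusted p = 0.0016) and AKR1C3 by 0.64 ± 0.14 (adjusted p = 0.00461). UGT2B17 fell by 0.86 ± 0.13 (adjusted p = 0.000292), while UGT2B15 differed by -0.28 ± 0.15 (adjusted p = 0.3). Another kept probe of UGT2B17 differed by -0.25 (adjusted p = 0.249). FKBP5 fell by 0.60 ± 0.14 (adjusted p = 0.00689). Against Intact1 alone UGT2B17, UGT2B15, FKBP5, AKR1C3 and HSD17B6 were all called, at -1.29, -0.61, -0.83, 0.84 and 1.01. None was called against Intact2 alone, at -0.44, 0.06, -0.37, 0.45 and 0.73 (adjusted p = 0.0516 to 0.953).

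Of the 35 androgen-induced genes, 11 fell and 3 rose in CRPC against intact tumors (15 and 3 adjusted over the list alone). The drug and organic anion transporter ABCC4 fell by 0.77 ± 0.09 and the amino acid transporter SLC43A1 by 1.00 ± 0.14, while the kallikrein KLK4 rose by 0.55 ± 0.08. The list's median was -0.17 (adjusted p = 0.000886; adjusted p = 0.498 with an estimated correlation; 0.00146 with the array set as a block). It was -0.27 within tumors 1 and 2 and -0.13 within tumors 3 and 4, where it did not pass (adjusted p = 0.182). Against Intact1 alone 14 genes fell and 1 rose (median -0.33), and against Intact2 alone 7 fell and 3 rose (median -0.08, adjusted p = 0.161). The androgen-repressed list had 4 of 12 rise and 2 fall (5 and 3 adjusted over the list alone; adjusted p = 0.815, adjusted p = 0.942 with an estimated correlation), with a median of 0.08 and a mean of -0.03.

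Some cell cycle genes fell in the average of CRPC1 and CRPC2 against all intact tumors. Of 30 mitosis genes 12 fell and 0 rose (24 fell adjusted over the list alone), among them the cyclins CCNB1 (-0.67 ± 0.16) and CCNA2 (-0.39 ± 0.10) and the spindle protein HMMR (-0.43 ± 0.10). The median was -0.33 (adjusted p = 2.23e-09; adjusted p = 0.498 with an estimated correlation; 3.53e-09 with the array set as a block), -0.44 within tumors 1 and 2 and -0.22 within tumors 3 and 4. Of 28 DNA replication genes 6 fell (15 fell and 1 rose adjusted over the list alone), including the sliding clamp PCNA (-0.44 ± 0.12), the helicase subunit MCM3 (-0.29 ± 0.08, but -0.19 and not called by another kept probe) and the polymerase subunit POLE2 (-0.37 ± 0.10). This list's median was -0.24 (adjusted p = 7.93e-06; adjusted p = 0.498 with an estimated correlation; 2.06e-05 with the array set as a block), -0.26 and -0.24 within the sets. Against Intact1 alone 13 mitosis and 5 replication genes fell, and against Intact2 alone 0 of either. The mean mitosis score (mean log2 level of the list, centered over all 20 arrays) was -0.35 in CRPC1 and 0.06 in CRPC2. It was 0.26 in Intact1 and 0.08 in Intact2. DNA replication scores were -0.11, 0.16, 0.29 and 0.18 in this order. For mitosis CRPC2 tumor 1 was at -0.43, and the other CRPC2 tumors at 0.10 to 0.38. The fall was thus seen in CRPC1, while CRPC2 lay near Intact2 on average. MCM3 was no longer called without CRPC2 tumor 1 (adjusted p = 0.0555), nor POLE2 without CRPC1 tumor 4 or CRPC2 tumor 1 or 2 (adjusted p = 0.0514 to 0.0532).

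Of 12 antigen presentation genes 5 fell and 0 rose (6 fell adjusted over the list alone), including the peptide transporter TAP1 (-0.77 ± 0.13) and HLA-DMA (-0.65 ± 0.11). The median was -0.16 (adjusted p = 0.0163; adjusted p = 0.498 with an estimated correlation; 0.0236 with the array set as a block), with -0.17 within tumors 1 and 2 and -0.15 within tumors 3 and 4 (adjusted p = 0.0519), and the call was lost without CRPC2 tumor 4 (adjusted p = 0.0638). Interferon-response genes had 3 of 17 fall (4 adjusted over the list alone), among them the ISG15 ligase HERC5 (-1.18 ± 0.20) and the RNA sensor IFIH1 (-0.52 ± 0.12). Their median of -0.19 passed at an adjusted p of 0.0488 (adjusted p = 0.647 with an estimated correlation) and not with the array set as a block (adjusted p = 0.0767). It was -0.15 within tumors 1 and 2, -0.22 within tumors 3 and 4 (adjusted p = 0.0719), -0.32 against Intact1 alone and -0.07 against Intact2 alone (adjusted p = 0.349). That call was also lost without Intact1 tumor 1 or 2, Intact2 tumor 1 or 4, CRPC1 tumor 2, 3 or 4, or CRPC2 tumor 2, 3 or 4 (adjusted p = 0.0507 to 0.0997), and the median was -0.29 without CRPC1 tumor 1.

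Neuroendocrine markers had 5 of 12 rise and 0 fall (5 rose and 2 fell adjusted over the list alone), among them the granins SCG2, CHGA (0.71 ± 0.13) and CHGB (0.46 ± 0.09). As a list they did not pass (median 0.14, adjusted p = 0.128; adjusted p = 0.498 with an estimated correlation). Within tumors 1 and 2 the list passed (median 0.16, adjusted p = 0.0466 in camera), and within tumors 3 and 4 it did not (0.14, adjusted p = 0.254). Against Intact1 alone 5 rose (median 0.12), and against Intact2 alone 1 (median 0.15). Metallothioneins had 2 of 9 rise (4 adjusted over the list alone), MT3 by 1.01 ± 0.14 and MT1H by 0.37 ± 0.12, with a median of 0.25 (adjusted p = 0.0133; adjusted p = 0.498 with an estimated correlation; 0.0103 with the array set as a block), 0.18 within tumors 1 and 2 (adjusted p = 0.236) and 0.38 within tumors 3 and 4. The list was no longer called without CRPC1 tumor 3 or CRPC2 tumor 4 (adjusted p = 0.0601 to 0.0653). MT1H was no longer called without any 1 of the 8 intact tumors, CRPC1 tumor 3 or 4, or any CRPC2 tumor (adjusted p = 0.0526 to 0.11). Metallothionein medians were 0.69 against Intact1 alone and -0.07 against Intact2 alone. Those of hypoxia and glycolysis genes were 0.50 and 0.34 against Intact1 alone and -0.48 and -0.54 against Intact2 alone, with 0.03 and -0.05 against all 8 intact tumors. Against all intact tumors their sign also changed with the array set. Within tumors 1 and 2 they were -0.25 and -0.27 (adjusted p = 0.0297 and 0.0232 in camera). Within tumors 3 and 4 they were 0.22 and 0.11 (adjusted p = 0.0719 for each in camera).

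Limma called 1716 genes in this comparison, and 3550 at an unadjusted p under 0.05. Median scaling gave 1240 rises and 545 falls. With the array set as a block 2061 genes changed, and within tumors 1 and 2 and within tumors 3 and 4 1484 and 412. The 8 CRPC and 8 intact tumors did not overlap for 1.28% of all genes, where chance gives 0.0155%, and all 163 of these genes were called. Of 44 named genes 40 were called. All 40 were called with the block and kept their direction within each array set, where 37 and 24 passed. They too were chosen from these arrays, so this is no separate support. Against Intact1 alone 2106 genes changed, and against Intact2 alone 523. Of the 40 named calls 39 held against Intact1 alone and 24 against Intact2 alone, where among others MT3 (0.09), CHGA (0.29), CHGB (0.33), HERC5 (-0.67) and IFIH1 (-0.40) were not called (adjusted p = 0.136 to 0.907). Host cell markers had 3 rise and 3 fall of 32, with a median of 0.00675.

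The third comparison sets castration-resistant tumors against tumors 1 day after castration. Of 35 androgen-induced genes 15 rose and 4 fell in CRPC tumors (17 and 5 adjusted over the list alone; adjusted p = 0.000188 in camera; adjusted p = 0.294 with an estimated correlation). PMEPA1 rose by 1.69 ± 0.12, SLC45A3 by 1.67 ± 0.14, KLK4 by 1.35 ± 0.09 and TMPRSS2 by 1.18 ± 0.18. UGT2B17 and UGT2B15 fell by 2.29 ± 0.16 and 2.19 ± 0.19. NPY rose by 3.00 ± 0.24 and the synaptic adhesion protein NRXN2 by 3.44 ± 0.23, while MGP fell by 3.20 ± 0.21. In all, 1198 genes rose and 1316 fell.

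Further large rises of genes whose arrays did not overlap were those of PLOD2, a collagen lysyl hydroxylase (3.19 ± 0.66, above background in 1 of 4 GNX tumors, but 0.40 and 0.59 and not called by its other kept probes), SCG2 (2.73 ± 0.37, in 2 of 4 GNX tumors), the ephrin receptor EPHB6 (2.43 ± 0.24, in 1 of 4 GNX tumors) and OR51E1 (2.37 ± 0.33). ALDH1A1 fell by 2.74 ± 0.33, and the adhesion protein CNTNAP2 by 2.41 ± 0.24. HPGD, which degrades prostaglandins, fell by 2.38 ± 0.29. HABP2, above background in 4 of 4 GNX and 0 of 8 CRPC tumors, was at least 2.64-fold lower (adjusted p = 5.27e-08). The other adjusted p-values lie between 9.35e-07 and 0.00207. FKBP5 rose by 0.74 ± 0.17, HSD17B6 by 0.95 ± 0.20 and KLK3 by 0.84 ± 0.25 (adjusted p = 0.0256), and AKR1C3 fell by 0.67 ± 0.17. KLK3 was no longer called without GNX tumor 1, 3 or 4 (adjusted p = 0.059 to 0.0857).

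ERG, which VCaP cells express from a TMPRSS2 fusion, was read by a pair of probes that moved apart. By the brighter probe ERG was 7.95 ± 0.29 (SD, n = 8) in intact, 6.77 ± 0.27 (SD, n = 4) in GNX and 7.75 ± 0.26 (SD, n = 8) in CRPC tumors. It fell by 1.18 ± 0.15 in GNX against intact (adjusted p = 3.43e-05), rose by 0.97 ± 0.15 in CRPC against GNX (adjusted p = 0.000152) and differed by -0.21 ± 0.12 in CRPC against intact (adjusted p = 0.354). By the other probe ERG differed by -0.03, -1.26 and -1.29 in these comparisons, and that probe was above background in 12 of 12 intact and GNX tumors and in 1 of 8 CRPC tumors. With the mean of both probes the CRPC difference from GNX was -0.14 (adjusted p = 0.632).

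The androgen-induced list had a median of 0.26 in CRPC against GNX (0.000204 as its adjusted p with the array set as a block). It was 0.15 within tumors 1 and 2 and 0.44 within tumors 3 and 4, and 0.17 without CRPC2 tumor 4. The androgen-repressed list had 6 of 12 fall and 1 rise (6 and 1 adjusted over the list alone), SI by -1.36 ± 0.11, at a median of -0.56 (adjusted p = 0.000741; adjusted p = 0.0487 with an estimated correlation; 0.00103 with the array set as a block), -0.65 and -0.53 within the sets.

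Of 28 DNA replication genes 20 rose and 0 fell (22 rose adjusted over the list alone), with CDC45 at 1.31 ± 0.17, MCM10 at 1.16 ± 0.13 and GINS2 at 1.00 ± 0.13. The median was 0.52 (adjusted p = 3.24e-13; adjusted p = 0.215 with an estimated correlation; 1.04e-12 with the array set as a block), 0.60 within tumors 1 and 2 and 0.49 within tumors 3 and 4. Mitosis genes had 2 of 30 fall (1 adjusted over the list alone), with a median of -0.12 (adjusted p = 0.37; adjusted p = 0.783 with an estimated correlation). Of 19 unfolded protein response genes 10 rose and 0 fell (12 and 1 adjusted over the list alone), CRELD2 by 1.30 ± 0.15, MANF by 0.89 ± 0.13 and HSPA5 by 0.79 ± 0.11. Their median was 0.39 (adjusted p = 4.14e-06; adjusted p = 0.26 with an estimated correlation; 8.17e-06 with the array set as a block), 0.47 and 0.31 within the sets.

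Glycolysis genes had 11 of 20 rise and 0 fall (14 rose adjusted over the list alone), including PFKP (1.15 ± 0.15), PFKL (0.63 ± 0.11) and PFKFB3 (2.24 ± 0.43). Another kept probe of PFKP was at 0.22 and not called, and another of PFKFB3 at 0.67. Their median was 0.65 (adjusted p = 5.94e-07; adjusted p = 0.294 with an estimated correlation), 0.28 within tumors 1 and 2 and 0.82 within tumors 3 and 4. Hypoxia genes had 8 of 18 rise and 0 fall (9 and 1 adjusted over the list alone), including NDRG1 (1.19 ± 0.13, also on the androgen-induced list), STC2 (1.52 ± 0.21) and DDIT4 (1.18 ± 0.18). The hypoxia median was 0.53 (adjusted p = 0.00031; adjusted p = 0.326 with an estimated correlation), 1.00 within tumors 3 and 4, and 0.08 within tumors 1 and 2, where the list did not pass (adjusted p = 0.127). Of 9 metallothioneins 6 rose (7 adjusted over the list alone), including MT3 (2.02 ± 0.17, above background in 1 of 4 GNX tumors), MT1G (1.65 ± 0.24) and MT1X (1.17 ± 0.21), at a median of 0.62 (adjusted p = 1.55e-05; adjusted p = 0.215 with an estimated correlation), 0.46 and 0.87 within the array sets. With the array set as a block the adjusted p-values of these lists were 7.76e-08, 0.000161 and 9.17e-06. Glycolysis scores ran from -0.46 to 0.42 in CRPC1 and from -0.50 to 0.95 in CRPC2, against -0.62 to -0.59 in GNX. Hypoxia scores ran from -0.48 to 0.52, from -0.35 to 0.75 and from -0.57 to -0.49 in this order. For both lists CRPC1 tumors 1 and 2 and CRPC2 tumor 1 lay nearest to GNX.

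Of 17 interferon-response genes 9 fell in CRPC against GNX and 0 rose (12 fell adjusted over the list alone), including TAP1 (-0.83 ± 0.16), the immunoproteasome subunit PSMB8 (-0.72 ± 0.14) and IFIH1 (-0.68 ± 0.14). Another kept probe of PSMB8 was at -0.44 and not called. The median was -0.68 (adjusted p = 9.86e-05; adjusted p = 0.294 with an estimated correlation; 0.000149 with the array set as a block), -0.36 within tumors 1 and 2 and -0.87 within tumors 3 and 4. Without GNX tumor 4 it was -0.26 (adjusted p = 0.00407), and IFIH1 was at -0.44. Glucocorticoid-induced genes (7 of 15 rose and 0 fell; 8 and 1 adjusted over the list alone; median 0.47) passed at an adjusted p of 4.93e-05, with adjusted p = 0.215 with an estimated correlation, and cholesterol synthesis genes (5 of 19 rose; 10 adjusted over the list alone; median 0.34) at 9.86e-05, with adjusted p = 0.294 with an estimated correlation. Within the array sets these medians were 0.39 and 0.63, and 0.33 and 0.30, and the blocked adjusted p-values were 4.32e-05 and 0.000161. Androgen inactivation and uptake genes had 4 of 11 fall and 1 rise (4 and 1 adjusted over the list alone), at a median of -0.20 (adjusted p = 0.0275; adjusted p = 0.282 with an estimated correlation; 0.0361 with the array set as a block), -0.30 and -0.11 within the sets, not passing in tumors 3 and 4 (adjusted p = 0.118). From both sets together the median was -0.13 without GNX tumor 1 and -0.31 without GNX tumor 2, and the call was lost without CRPC1 tumor 1 (adjusted p = 0.0555). This list shares its UGT2B genes with the androgen-repressed list, so it is no separate support.

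Limma called 2514 genes between CRPC and GNX tumors, and 4125 at an unadjusted p under 0.05. The array set as a block gave 2903, and fits within the array sets 1379 and 1374. Tumors of these conditions did not overlap for 1397 genes, where chance gives 0.404% of all genes, and 1328 of these genes were called. All 41 genes named for this comparison were called, all 41 with the block, and 37 and 40 within tumors 1 and 2 and within tumors 3 and 4, with 1 direction throughout. Their choice from these arrays largely fixes that direction. Host cell markers had 4 rise and 2 fall of 32, with a median of 0.04.

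**Figure D3:**
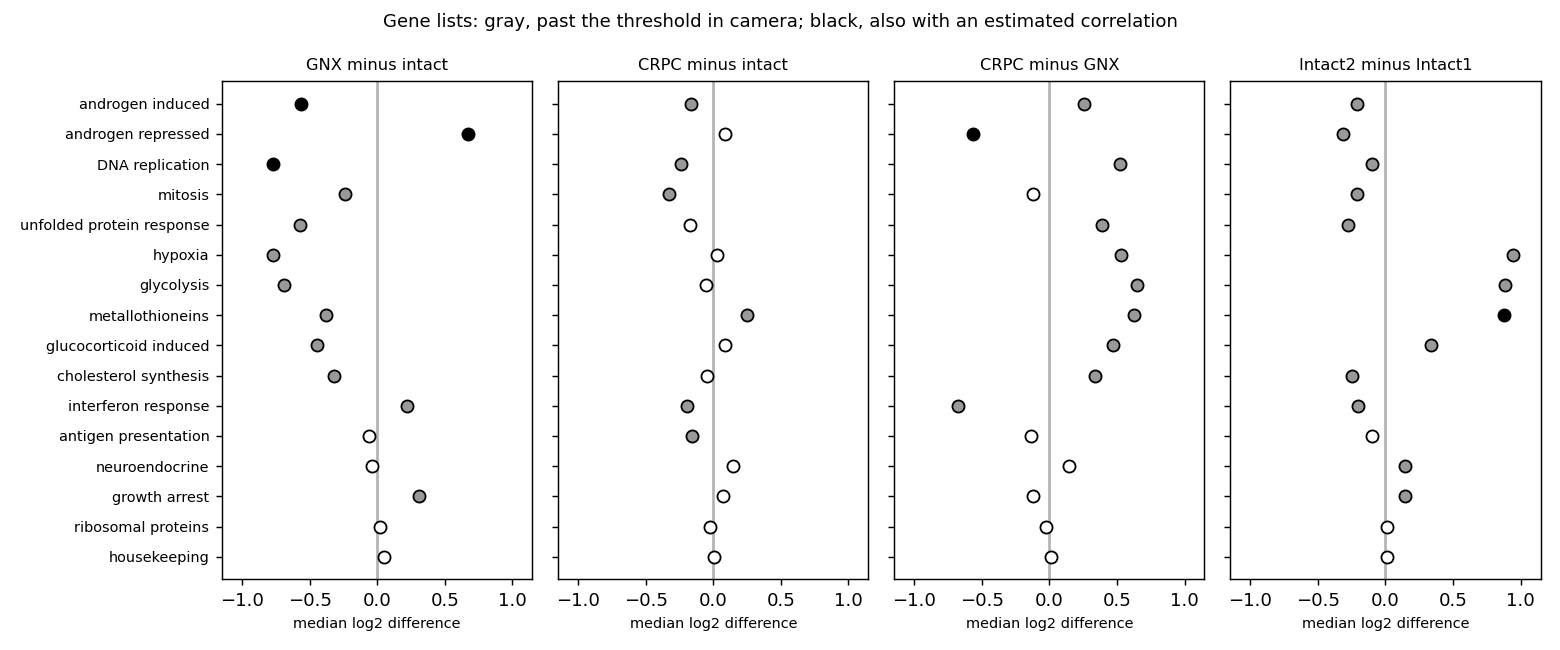
Median log2 difference of the measured genes of 16 gene lists in 4 comparisons. Gray points passed camera with the preset correlation of 0.01, black points passed also with an estimated correlation, and open points did not pass.

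The changes after 1 day and in castration-resistant tumors were set against each other across the 12696 genes, which are not independent replicates. Of 1015 genes that rose in GNX tumors, 179 (17.6%) also rose in CRPC and 72 (7.09%) fell. Of 934 that fell, 175 (18.7%) also fell in CRPC and 60 (6.42%) rose. Both comparisons use the same intact arrays, which alone favors shared directions. Against all 8 intact tumors FKBP5 was lower and AKR1C3 higher in both comparisons, whereas UGT2B17 was higher in GNX (1.43 ± 0.16) and lower in CRPC (-0.86 ± 0.13); none of these CRPC calls held against Intact2 alone (adjusted p = 0.293, 0.184 and 0.174). Pearson's r of the log2 changes was 0.219 and Spearman's rho 0.26, where groups with no effect against shared intact arrays gave a mean r of 0.406 in 100 simulations (0.382 to 0.441). The covariance was 0.0165 against a simulated 0.00627, a difference of 0.0103. The simulations held noise only, so their r cannot be set against an r that also holds group effects.

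With split controls, GNX against Intact1 and CRPC against Intact2 gave r = 0.205. Of 861 genes that rose in the former, 56 rose and 22 fell in the latter, where independent lists would share 18.4 and 17.1, and of 811 that fell, 46 fell and 20 rose (16.1 and 17.3). GNX against Intact2 and CRPC against Intact1 gave r = -0.145. Of 751 that rose, 75 rose and 128 fell (63.9 and 60.6), and of 752 that fell, 90 fell and 147 rose (60.7 and 64.0).

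The groups of intact tumors also differed from each other; the labels state no purpose for this comparison. PLOD2 was higher in Intact2 than in Intact1 by 4.48 ± 0.76 (n = 4 and 4), from 6.63 ± 0.30 (SD) to 11.10 ± 0.25 (SD). Its standard error of 0.76 comes from the model's spread over all 5 groups, and PLOD2 spread widely within CRPC1 and CRPC2. The glycolysis regulator PFKFB3 rose by 3.15 ± 0.50, the hypoxia-induced ANKRD37 by 2.09 ± 0.30 and the chemokine CCL2, which recruits monocytes, by 3.88 ± 0.70. The heat-shock gene HSPA6 rose by 3.99 ± 0.71, above background in 1 of 4 Intact1 tumors. Other kept probes gave smaller differences: 2.05 ± 0.39 for HSPA6, 0.99 ± 0.21 and 1.12 ± 0.32 for PLOD2 and 1.00 ± 0.26 for PFKFB3, the last 2 not passing (adjusted p = 0.0799 and 0.053). In all, 224 genes rose and 78 fell.

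**Figure D4:**
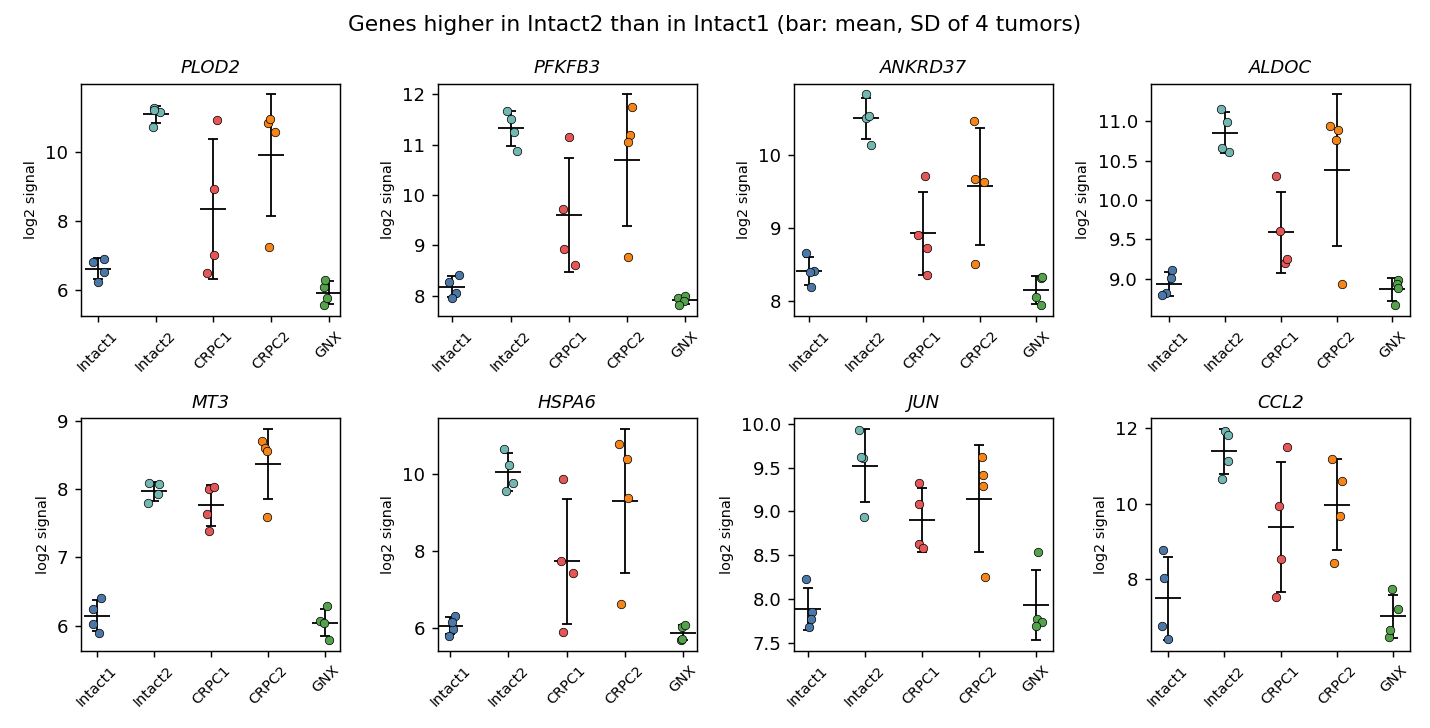
Log2 signal of 8 genes in each of the 20 tumors, 1 point per tumor, with the mean and SD of the 4 tumors of each group. PLOD2 is at 6.63 in Intact1, 11.10 in Intact2 and 5.94 in GNX on average, and spreads widely within CRPC1 and CRPC2.

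Of 18 hypoxia genes 11 rose in Intact2 and 0 fell (13 rose adjusted over the list alone), including MXI1 (0.82 ± 0.11) and STC2 (1.55 ± 0.24). Other kept probes of MXI1 (0.21 and 0.44) and of the glycolysis gene PFKP (0.23) did not pass. The median was 0.95 (adjusted p = 2.83e-15; adjusted p = 0.0892 with an estimated correlation; 4.01e-16 with the array set as a block), 0.86 within tumors 1 and 2 and 1.07 within tumors 3 and 4. Of 20 glycolysis genes 11 rose (16 rose and 1 fell adjusted over the list alone), including PFKP (1.20 ± 0.18) and the aldolase ALDOC (1.92 ± 0.32). Their median was 0.89 (adjusted p = 4.99e-14; adjusted p = 0.144 with an estimated correlation; 1.09e-15 with the array set as a block), 0.79 and 0.96 within the sets. Metallothioneins had 5 of 9 rise (7 adjusted over the list alone), among them MT3 (1.83 ± 0.20, above background in 2 of 4 Intact1 tumors), MT2A (1.31 ± 0.21) and MT1X (1.56 ± 0.25). The median was 0.88 (adjusted p = 1.64e-10; adjusted p = 0.0422 with an estimated correlation; 5.63e-11 with the array set as a block), 0.86 and 0.90 within the sets.

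Some stress genes also rose. Of 15 heat-shock genes 2 rose (5 adjusted over the list alone), HSPA1B by 2.15 ± 0.40 and DNAJB1 by 1.86 ± 0.38. The heat-shock median was 0.34 (adjusted p = 0.000285; adjusted p = 0.33 with an estimated correlation; 0.000329 with the array set as a block), 0.74 within tumors 3 and 4 and 0.01 within tumors 1 and 2, where the list did not pass (adjusted p = 0.413). Immediate-early genes had 3 of 18 rise (5 adjusted over the list alone): JUN by 1.64 ± 0.27, the phosphatase DUSP1 by 1.11 ± 0.26, and FOS, not above background in any Intact1 tumor and at least 3.84-fold higher (adjusted p = 0.00465). That list's median was 0.21 (adjusted p = 0.00081; adjusted p = 0.176 with an estimated correlation; 0.000314 with the array set as a block), 0.21 and 0.22 within the sets. Glucocorticoid-induced genes had 4 of 15 rise (6 adjusted over the list alone; median 0.34; adjusted p = 0.00068; adjusted p = 0.154 with an estimated correlation), namely MT2A, MT1X, DUSP1 and DDIT4, each of which is also on another list of this comparison, with 0.37 and 0.31 within the sets and a blocked adjusted p of 0.000373. The heat-shock median was 0.19 without Intact2 tumor 4, where DNAJB1 was no longer called (adjusted p = 0.074). DUSP1 was no longer called without any 1 of the 4 Intact1 tumors or without Intact2 tumor 1, 3 or 4 (adjusted p = 0.0573 to 0.126).

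Of 35 androgen-induced genes 2 fell in Intact2 (10 fell and 1 rose adjusted over the list alone), the prostatic acid phosphatase ACP3 by 1.03 ± 0.18 and SLC45A3 by 0.67 ± 0.16. The median was -0.21 (adjusted p = 4.88e-05; adjusted p = 0.168 with an estimated correlation; 6.04e-05 with the array set as a block), -0.30 within tumors 1 and 2, -0.22 within tumors 3 and 4, and -0.32 without Intact2 tumor 2. The androgen-repressed list had 1 of 12 fall and 0 rise (5 fell adjusted over the list alone), with a median of -0.32 (adjusted p = 0.0194; adjusted p = 0.12 with an estimated correlation; 0.0227 with the array set as a block), -0.27 and -0.28 within the sets. The largest falls of genes whose arrays did not overlap were those of CWH43 (-1.78 ± 0.41), CNTNAP2 (-1.15 ± 0.28) and the membrane protein ITM2A (-1.07 ± 0.26). CNTNAP2, ITM2A and SLC45A3 were each no longer called without Intact1 tumor 1, 2 or 3 or Intact2 tumor 1, 3 or 4 (adjusted p = 0.0619 to 0.155), nor CWH43 without Intact1 tumor 1 or 2 or Intact2 tumor 1 or 4 (adjusted p = 0.0906 to 0.108). In this comparison 18 of 34 lists passed camera and 1 passed with an estimated correlation, that of the metallothioneins.

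Limma called 302 genes between Intact2 and Intact1, and 2072 at an unadjusted p under 0.05. Median scaling gave 220 rises and 45 falls, quantile normalization without background correction 244 and 119, and no filter on dim probes 110 and 17. With the array set as a block 487 were called, and within the array sets 190 and 113. Without Intact1 tumor 1, 2 or 3 the count was 134, 130 or 179, and without Intact2 tumor 1, 3 or 4 it was 151, 182 or 113. The groups did not overlap for 11.8% of all genes, where chance gives 2.86%, and 295 of these genes were called. All 22 named genes were called with the block and kept their direction within each array set, where 16 and 17 passed. Being chosen from the same arrays largely fixes that direction. Host cell markers had 1 rise of 32, with a median of 0.09.

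No single gene was called between CRPC2 and CRPC1 in the main model with all arrays. Mitosis genes had a median difference of 0.44 in CRPC2 against CRPC1, with 0 of 30 called over all genes (23 rose adjusted over the list alone). The list passed camera (adjusted p = 4.01e-23; adjusted p = 0.233 with an estimated correlation; 7.8e-22 with the array set as a block), with 0.18 within tumors 1 and 2 and 0.67 within tumors 3 and 4. The kinetochore gene CENPF differed by 0.57 ± 0.16 (adjusted p = 0.508) and CCNA2 by 0.57 ± 0.14 (adjusted p = 0.498). Glycolysis genes had a median of 0.57 (6 rose adjusted over the list alone; adjusted p = 9.89e-13; adjusted p = 0.233 with an estimated correlation; 3.15e-14 with the block), 0.39 and 0.70 within the sets, with PFKFB4 at 1.24 ± 0.53 (adjusted p = 0.702) and hexokinase HK2 at 1.09 ± 0.46 (adjusted p = 0.701). DNA replication genes had a median of 0.24 (4 rose adjusted over the list alone; adjusted p = 5.14e-12; adjusted p = 0.233 with an estimated correlation; 3.75e-11 with the block), 0.13 and 0.41 within the sets, with RRM2 at 0.64 ± 0.16 (adjusted p = 0.498) and TYMS at 0.60 ± 0.17 (adjusted p = 0.508). The glycolysis median was 0.37 without CRPC2 tumor 4. Hypoxia genes had a median of 0.41 (adjusted p = 2.64e-06 in camera with the block, not passing with an estimated correlation), 0.37 within each set and 0.25 without CRPC2 tumor 4. That rise was smaller than the 0.95 of Intact2 against Intact1, so the negative interaction of this list is no fall in CRPC2. Without CRPC2 tumor 1, CENPF, CCNA2, HK2, RRM2 and TYMS were called.

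Limma called 0 genes between CRPC2 and CRPC1, 942 at an unadjusted p under 0.05, with a smallest adjusted p of 0.145. The array set as a block gave 3, and fits within the array sets 0 and 28. Without CRPC2 tumor 1 the count was 63, without CRPC1 tumor 1 it was 5, and without CRPC1 tumor 2 it was 1. The difference between CRPC2 and CRPC1 against that between Intact2 and Intact1 was tested as an interaction. Limma called 0 genes in it, with 1503 at an unadjusted p under 0.05 and a smallest adjusted p of 0.112. Which intact group belongs to which CRPC group is not stated in the labels, so the interaction follows the group numbers alone. The array set as a block gave 3 and fits within the sets 0 and 13. It gave 6 without CRPC1 tumor 1, 3 without Intact1 tumor 4, 2 without CRPC1 tumor 2 and 1 without Intact2 tumor 2. Host cell markers had 0 change of 32 in either test.

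In the interaction, the mitosis list had a median of 0.63 (17 rose adjusted over the list alone; adjusted p = 2.42e-18; adjusted p = 0.185 with an estimated correlation; 1.14e-17 with the block), 0.32 and 0.89 within the array sets. BIRC5 was at 0.87 ± 0.27 (adjusted p = 0.274) and CDC20 at 0.87 ± 0.24 (adjusted p = 0.208). The DNA replication list had a median of 0.33 (4 rose adjusted over the list alone; adjusted p = 5.95e-09; adjusted p = 0.202 with an estimated correlation; 1.88e-08 with the block), 0.14 within tumors 1 and 2, where it did not pass (adjusted p = 0.113), and 0.48 within tumors 3 and 4, with RRM2 at 1.07 ± 0.23 (adjusted p = 0.112) and UHRF1 at 0.77 ± 0.25 (adjusted p = 0.291). Hypoxia genes had a median of -0.68 (2 fell adjusted over the list alone; adjusted p = 6.46e-06; adjusted p = 0.202 with an estimated correlation; 1.66e-06 with the block), -0.47 and -0.80 within the sets, with ADM at -1.76 ± 0.77 (adjusted p = 0.461) and VEGFA at -1.66 ± 0.74 (adjusted p = 0.464).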

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

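Of the tests weighed here, those of host RNA, of stress at collection, of the ERG probe in intact and GNX tumors, of mitosis probes at background and of the assignments of arrays were chosen after the results were seen. Of 780 groups of 4 tumors examined, 39 held a tumor lying far from the other 3, and chance alone would do so in about 1 in 20 groups. None was left out of any fit.

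Intact2 tumor 3 had 18668 probes above background, where the other 3 had 20215 to 20408. The interferon score of GNX tumor 4 was 1.128, far above the 0.0800 to 0.257 of the other GNX tumors. Further list scores lying far from those of the other 3 tumors were those of androgen-induced genes in GNX tumor 2 (-0.2952), androgen-repressed genes in CRPC1 tumor 4 (-0.3254), growth arrest genes in CRPC1 tumor 2 (-0.09061), unfolded protein response genes in CRPC2 tumor 3 (-0.172), WNT and NOTCH genes in GNX tumor 2 (0.1143), host endothelial markers in GNX tumor 1 (-0.08176) and housekeeping genes in Intact2 tumor 2 (0.05645).

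CRPC2 tumor 1 lay far below the other CRPC2 tumors for PLOD2 (7.272, others at least 10.6), and also apart for ADM (7.228), PFKP (10.44), ALDOC (8.941), MT3 (7.596) and RRM2 (7.243). Other log2 levels far from those of the same group were NPY (13.28) and STEAP4 (7.238) in CRPC2 tumor 4, KLK2 in CRPC2 tumor 3 (12.5), AKR1C3 (10.61) and CHGA (10.54) in CRPC1 tumor 1, SOX9 (10.15) and MT2A (10.7) in CRPC1 tumor 2, and ODC1 (10.94) and HMGCS1 (9.916) in CRPC1 tumor 4. In GNX they were PCNA (8.888), NOTCH1 (7.799) and MT2A (11.18) in tumor 2 and JUN (8.535) in tumor 3. In Intact1 they were SESN1 in tumor 1 (7.735), MT1X in tumor 2 (10.47), TTK (8.828) and CEBPD (10.37) in tumor 3, and CCNB1 (8.374), EBP (9.233) and PFKL (9.592) in tumor 4. In Intact2 they were HLA-DMA in tumor 1 (8.51), TRPM8 (12.38) and MT1G (8.742) in tumor 2 and EPHB6 in tumor 3 (6.334).

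The step from CRPC1 to CRPC2 differed from the step from Intact1 to Intact2 in 13 lists, none of which passed with an estimated correlation. The labels do not say that Intact1 belongs to CRPC1 and Intact2 to CRPC2, so these steps follow the group numbers alone. Median differences between the steps were 0.35 for androgen-induced genes, 0.40 for cholesterol synthesis, 0.31 for fatty acid synthesis, 0.13 for polyamine synthesis, 0.33 for DNA replication, 0.63 for mitosis and 0.36 for the unfolded protein response. They were -0.28 for growth arrest, -0.68 for hypoxia, -0.32 for glycolysis, 0.12 for oxidative phosphorylation, -0.60 for glucocorticoid-induced genes and -0.68 for metallothioneins. With the array set as a block all 13 passed (adjusted p at most 0.0468 in limma's camera). Within tumors 1 and 2 the lists of oxidative phosphorylation (0.00143), glucocorticoid-induced genes (-0.23), metallothioneins (-0.26), growth arrest (-0.17), DNA replication (0.14) and polyamine synthesis (0.10) did not pass (adjusted p = 0.0628 to 0.904), against 0.19, -1.06, -0.57, -0.32, 0.48 and 0.10 within tumors 3 and 4. Within tumors 3 and 4 glycolysis (-0.19), the unfolded protein response (0.31) and polyamine synthesis did not pass (adjusted p = 0.0676 to 0.214), against -0.47 and 0.41 for the former lists within tumors 1 and 2. The androgen-induced, cholesterol synthesis, fatty acid synthesis, mitosis and hypoxia lists passed within each set, at 0.27, 0.56, 0.37, 0.32 and -0.47 in tumors 1 and 2 and 0.31, 0.30, 0.13, 0.89 and -0.80 in tumors 3 and 4. From both sets together the glycolysis median was -0.03 without CRPC2 tumor 1, -0.15 without CRPC1 tumor 3 and -0.54 without CRPC2 tumor 4, and that of glucocorticoid-induced genes -0.33 without CRPC1 tumor 3 and -0.38 without CRPC2 tumor 4. That of polyamine synthesis was 0.23 without CRPC1 tumor 1 and 0.09 without CRPC1 tumor 2, and that of cholesterol synthesis 0.27 without Intact2 tumor 1. In limma's camera the glycolysis list was no longer past the threshold without Intact2 tumor 4, CRPC1 tumor 3 or CRPC2 tumor 1 (adjusted p = 0.0521 to 0.604). The same held for oxidative phosphorylation without CRPC1 tumor 3 or 4 or CRPC2 tumor 3 (adjusted p = 0.0534 to 0.0574) and for polyamine synthesis without CRPC1 tumor 2 or 3 or CRPC2 tumor 1 or 3 (adjusted p = 0.0534 to 0.0672).

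Whether as many genes would be called in groups drawn by chance was tested by splitting the same arrays into groups of the same sizes. The real split alone reached its count in 1 of 100 splits for CRPC against intact (1244 genes, at most 1053 otherwise), 1 of 100 for GNX against intact (1605, at most 362) and 1 of 100 for CRPC against GNX (1967, at most 139). Among CRPC and intact tumors, splitting tumors 1 and 2 from tumors 3 and 4, which was not drawn, gives 1627 genes. That is more than the 1244 of the real split in the same fit, which held 2 groups and these arrays alone. The main model, fitted to all 5 groups with the array set as a block, called 2061 genes between CRPC and intact tumors. It called 1484 and 412 within the sets. Counts of that model cannot be set against those of the splits. For Intact2 against Intact1, 2 of 35 splits reached 246 genes, the other being tumors 1 and 2 against tumors 3 and 4 with 928, so these splits do not exclude chance and show a structure of the arrays by set. The main model with the array set as a block called 487 genes between Intact2 and Intact1, with 190 and 113 within the sets. These counts too cannot be set against those of the splits. A count of 0 is reached by every split (35 of 35 for CRPC2 against CRPC1, at most 961 by array set, and 100 of 100 for the interaction, at most 191), so splits say nothing about those counts, which limma gave with 942 and 1503 genes at an unadjusted p under 0.05.

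The hypoxia and glycolysis genes, 38 together, were higher in Intact2 than in Intact1 by a median of 0.922. An array set could not account for it, since the lower of the medians within the sets was 0.827, nor could 1 tumor, since the lowest median without any tumor was 0.842. A larger share of mouse RNA could not be told, with host markers at 0.0822 (0.0895 without ERG, which VCaP cells express) and a standard error over genes, not tumors, larger than the former. Stress at collection remains possible: immediate-early and heat-shock genes, 33 together, were higher by 0.277 ± 0.166 (SE over genes, which are not independent, and not over tumors). Heat-shock genes had a median of 0.01 within tumors 1 and 2 and 0.74 within tumors 3 and 4. Immediate-early genes had 0.21 and 0.22 there. Less oxygen in larger tumors is another possibility that no deposited value tests.

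The ERG probes moved apart between GNX and CRPC tumors. A dim probe lost in background could make such a split, and the dimmer probe was above background on 13 of 20 arrays. It was so on 12 of 12 arrays of intact and GNX tumors and 1 of 8 of CRPC tumors, and a floor in CRPC tumors can only make its fall from GNX look smaller, which argues against background. The array sets are excluded, with the probes at least 2.19 apart within each. The annotation names a different ERG transcript for each probe. Whether a probe reads only that transcript, and whether transcripts made the split, the deposited values cannot test.

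DNA replication genes fell more than mitosis genes in GNX tumors, by a gap of 0.532 between the medians. Mitosis probes at background could hide a fall, but 30 of 30 were above it on all 12 arrays, and over genes of both lists above background there the gap was 0.563. Weaker binding by the mitosis probes stays open, since the difference of 0.796 between the lists' median levels compares probes that share no scale. The array sets are excluded, with a gap of at least 0.506 within each. An exact permutation test over all assignments of the 12 arrays gave p = 0.00202, two-sided, the smallest possible. That test was chosen after the gap was seen, and its p is not corrected for this, so chance is not excluded. Cells that no longer entered DNA synthesis while others went on to mitosis may also give such a gap, which was not tested.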

How the results depend on the processing

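The alternatives were fixed before the data were examined, apart from the array set (as a block, or within each set), the offset of 50 and each intact group alone, which were chosen after seeing the data. A block by slide was not run, because the files name no slides. Where a value moved, the cause was not tested unless it is said.

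Of the comparisons of named genes with alternatives 4424 stayed the same, 153 became weaker, 8 stronger and 1 reversed; of those of lists, by the direction camera gives, 5280, 182, 146 and 6; of counts and agreement 179 stayed, 45 moved and 1 reversed. Quantile normalization without background correction, median scaling and the replicate block left the total count of each of the first 3 comparisons within 1.5-fold. With the replicate block the counts were 1937, 2184 and 2773, and 419 for Intact2 against Intact1. The deposited values are the same as quantile normalization without background correction and gave the same counts. They are no separate alternative, although the totals above include both. With median scaling the falls in CRPC against intact went from 819 to 545 and the rises from 897 to 1240. With only the compared groups in the fit, 1554 genes were called in CRPC and 2032 in GNX against intact. CRPC against GNX then had 1978 and Intact2 against Intact1 246. Deviations from the group means were correlated between arrays of different groups. They correlated at 0.0770 to 0.408 for arrays of the same number and at 0.127 to 0.436 for the same set with another number. Across sets they correlated at -0.431 to -0.0803. The mean correlation was highest with the own number in 6 of 20 arrays, so the numbers do not pair.

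Without a filter 1075 genes changed in CRPC and 1281 in GNX against intact, and 127 in Intact2 against Intact1; more dim probes are tested there. With probes above background on all 20 arrays the interaction called 3. Array weights gave 630 for Intact2 against Intact1 and 2 for CRPC2 against CRPC1. A difference of at least 1 on the log2 scale, a stricter rule by construction, left 114, 153, 255 and 77 genes in CRPC against intact, GNX against intact, CRPC against GNX and Intact2 against Intact1. The array set as a block gave 487 for Intact2 against Intact1, 3 for CRPC2 against CRPC1 and 3 for the interaction. Fewer samples entered the fits within tumors 1 and 2 (868 for GNX against intact, 1379 for CRPC against GNX, 190 for Intact2 against Intact1) and within tumors 3 and 4 (412 for CRPC against intact, 719, 1374, 113, 28 for CRPC2 against CRPC1 and 13 for the interaction). Against Intact2 alone 523 genes changed in CRPC. Of 71 list shifts, 5 passed with an estimated correlation.

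Leaving out 1 tumor at a time gave 1250 to 2247 genes for CRPC against intact, 1366 to 1816 for GNX against intact, 1779 to 2620 for CRPC against GNX, 113 to 334 for Intact2 against Intact1, 0 to 63 for CRPC2 against CRPC1 and 0 to 6 for the interaction. List shifts numbered 68 to 79, and agreement was 0.186 to 0.248.

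Agreement between castration effects was 0.219, 0.239 without a filter, 0.205 with GNX against Intact1 and CRPC against Intact2, and reversed to -0.145 with GNX against Intact2 and CRPC against Intact1. ERG in CRPC against GNX reversed to -0.14 with the mean of the kept probes, which by construction adds the probe that moved the other way. The direction in camera and the median both reversed for cholesterol synthesis in Intact2 against Intact1 within tumors 3 and 4 (0.0317), glycolysis in CRPC against Intact1 alone (0.34) and metallothioneins in CRPC against Intact2 alone (-0.0691). The direction in camera reversed while the median kept its sign for DNA replication in Intact2 against Intact1 within tumors 1 and 2 (-0.10 to -0.0209), glucocorticoid-induced genes in CRPC2 against CRPC1 within tumors 1 and 2 (0.01 to 0.162) and hypoxia in CRPC against Intact1 alone (0.03 to 0.50). Their cause was not tested.

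Signal over background limits what is seen: 18266 to 21741 of 47323 probes stood above background, and genes below it were not tested.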

Other observations

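The tests behind this part follow the fixed rule for naming genes, and no hypothesis was added after the results were seen. In GNX against intact tumors 6 of 13 genes of the amino acid response fell and 1 rose (8 and 1 adjusted over the list alone), among them the lipoprotein receptor VLDLR (-1.91 ± 0.13, adjusted p = 4.25e-08), the folate enzyme MTHFD2 (-0.54 ± 0.11, adjusted p = 0.00285) and the serine synthesis enzyme PSAT1 (-0.49 ± 0.11, adjusted p = 0.00428). The list's median was -0.27 (limma's camera, adjusted p = 0.000291; adjusted p = 0.161 with an estimated correlation; 0.000358 with the array set as a block), -0.36 within tumors 1 and 2 and -0.24 within tumors 3 and 4. Against Intact1 alone 4 fell (median -0.29), and against Intact2 alone 6 fell and 1 rose (median -0.17). In CRPC against GNX 5 of these genes rose and 2 fell (5 and 2 adjusted over the list alone), at a median of 0.12 (adjusted p = 0.0185; adjusted p = 0.311 with an estimated correlation; 0.0211 with the array set as a block), 0.15 and 0.08 within the array sets, not passing in tumors 3 and 4 (adjusted p = 0.0782). From both sets together the median was 0.07 without CRPC2 tumor 4, and the call was lost without CRPC2 tumor 4 or GNX tumor 2 (adjusted p = 0.0574 to 0.0587).

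Some genes changed in CRPC against intact tumors although their lists did not pass. In polyamine synthesis, ornithine decarboxylase ODC1 fell by 1.20 ± 0.15 (limma, adjusted p = 3.96e-05), while arginase ARG2 rose by 0.87 ± 0.13 (adjusted p = 0.00018) and spermine oxidase SMOX by 0.52 ± 0.11 (adjusted p = 0.00548). In WNT and NOTCH signaling, the receptor NOTCH1 fell by 0.68 ± 0.11 (adjusted p = 0.00044) and the transcription factor SOX9 by 0.78 ± 0.16 (adjusted p = 0.00374), while the WNT inhibitor RNF43 rose by 0.60 ± 0.11 (adjusted p = 0.00175). The list medians were 0.02 (adjusted p = 0.984) and -0.07 (adjusted p = 0.624).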
